A study of Homo sapiens with 10 samples.

How the data were processed

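Total RNA of A375 melanoma cells was labelled with biotin and hybridised to Affymetrix Clariom S human HT arrays, 1 array per sample. Per the labels, 5 arrays came from control cells and 5 from cells plated with doxycycline at 2 µg/ml for 4 days, and the arrays of each group are called biological replicas. Nothing in the labels says whether they came from separate cultures or days, so p-values measure the spread between these samples, which may be technical in part. The series title names Omomyc, and none of the 10 arrays analysed here is labelled as doxycycline-treated cells without Omomyc. An effect of doxycycline alone is therefore part of the comparison.

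The deposited values are log2 expression values for 18569 probe sets, made with RMA (background correction, quantile normalization between arrays and summary of the probes of a set), per the submitters' processing notes. The version of the RMA software, the library file and any filter on probe sets are not given in the sources used here. The values ran from 1.14 to 12.9, with first quartiles of 2.80 to 2.94 and medians of 5.02 to 5.10 on the 10 arrays, so the log2 scale and near-equal distributions were checked on the values themselves. RMA gives each array the same distribution before summary, so a change of total RNA per cell would not be seen, and a fold change is relative to the other genes of the array. Probe signal near the background compresses fold changes of dim genes. Scanner files were not used here.

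Gene symbols came from the platform annotation paired with the value table, which gave 17511 probe sets 1 symbol each, 0 several symbols and left 1058 unnamed here. The names were current in the RefSeq gene table for GRCh38.p14, which was otherwise used only for the order of neighbouring genes. Of 17492 genes, 17 had more than 1 probe set, and the probe set with the highest mean over the 10 arrays stood for the gene. All probe sets were tested without a filter, and unnamed ones were counted but not named (361 of the changed ones). Probe sets of near-identical genes, such as histones, protocadherins and metallothioneins, can share hybridisation.

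Doxycycline was compared with control with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with default settings, group as the only term, two-sided tests and Benjamini-Hochberg adjustment over all 18569 probe sets. A probe set was called at an adjusted p under 0.05, and a second count added a log2 fold change of at least 1 in size. Errors are the moderated standard errors of limma for fold changes and SDs over 5 arrays for levels. The median residual SD was 0.165 log2 units and the median standard error 0.103. Array correlations over all probe sets were 0.993 to 0.997 within control, 0.990 to 0.996 within doxycycline and 0.970 to 0.976 between groups, and no 2 arrays held identical values.

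Before the data were examined, 39 gene lists were written from general knowledge to fit the cell line and a block of MYC. They covered the MYC network and its targets, ribosome and translation, metabolism, cell cycle, cell death, melanoma states, signalling, stress, immune response, mitochondria, lysosome, matrix, clock, handling, and markers of keratinocytes, fibroblasts, endothelium, leukocytes and epithelial lines. The list of mitochondrially encoded genes had 0 measured members, which left 38 lists. Each was tested with camera of limma at a preset inter-gene correlation of 0.01 and again with the correlation estimated per list, with Benjamini-Hochberg adjustment over the 38 lists. Calls within a list were also counted with p values adjusted over the list alone.

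Genes were named by a rule fixed in advance. It took the 12 highest and 12 lowest fold changes among called probe sets with 1 symbol whose groups did not overlap, every measured member of the MYC network, and up to 4 called members of each described list by size of change, or more where a count of at most 5 was spelled out. Any gene named outside this rule was chosen after its values were seen.

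The model and the list tests were tested on simulated data with the spread of these arrays. In a simulated comparison of doxycycline with control over 18569 probe sets, 50 probe sets were changed at each of 4 sizes. Changes of 0.25, 0.5, 1 and 2 log2 units were recovered in 0%, 56%, 100% and 100% of cases, with 3 false calls among 131. The share of changed probe sets was far smaller than the 38.1% called in the real comparison, and the adjusted p depends on that share. These rates therefore do not carry over to the real comparison, where some changes of about 0.27 log2 units were called. A list shifted by 0.3 log2 units was the single list called of 38, under either correlation. Simulated probe sets were drawn independently of each other, so this does not show how often lists of correlated genes are called falsely. Estimated correlations within the real lists reached 0.437, for ribosomal proteins.

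Alternatives fixed in advance were filters on dim probe sets, median centring, quantile normalization and cyclic loess of the deposited values, trend and robust variance, array weights, the replicate number as a block, a minimum fold of 1.2 (treat), exact permutation per probe set, leaving out each array, the mean of several probe sets per gene, a stricter threshold and other list tests. Counts per list without doxycycline array 1 were added after that array was seen to stand apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.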

Results

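RNA of A375 cells, an established human melanoma line that carries an activating BRAF mutation, was measured on 10 Clariom S arrays. Control cells and cells plated with doxycycline at 2 µg/ml were frozen on day 4, with 5 arrays in each group. The series title names Omomyc, a mutant of the dimerisation domain of MYC that binds MYC and MAX and blocks MYC-driven transcription, and asks how it affects growth of this line. Doxycycline is the usual inducer of such transgenes, but the labels do not describe the construct, and the comparison made here is therefore doxycycline against control. Median log2 signal lay between 5.02 and 5.10 on the 10 arrays, and the number of arrays limits the precision.

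Doxycycline-treated A375 cells had lower RNA signal for DNA replication, mitosis, amino acid supply, nucleotide synthesis and ribosome production genes, and higher signal for interferon-stimulated and lysosomal genes. All 46 measured genes of G2/M and mitosis and 40 of 45 genes of G1/S and DNA replication fell, with median log2 fold changes of -1.19 and -1.30. The amino acid response genes controlled by the transcription factor ATF4 fell in 28 of 32 cases, among them the cystine transporter gene SLC7A11, which was 14.3-fold lower. Of the interferon response genes 24 of 37 rose, and IFIT1, an antiviral RNA-binding protein, was 7.90-fold higher. Among 18569 probe sets 7078 changed (38.1%), 3875 of them higher and 3203 lower with doxycycline.

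**Figure D1:**
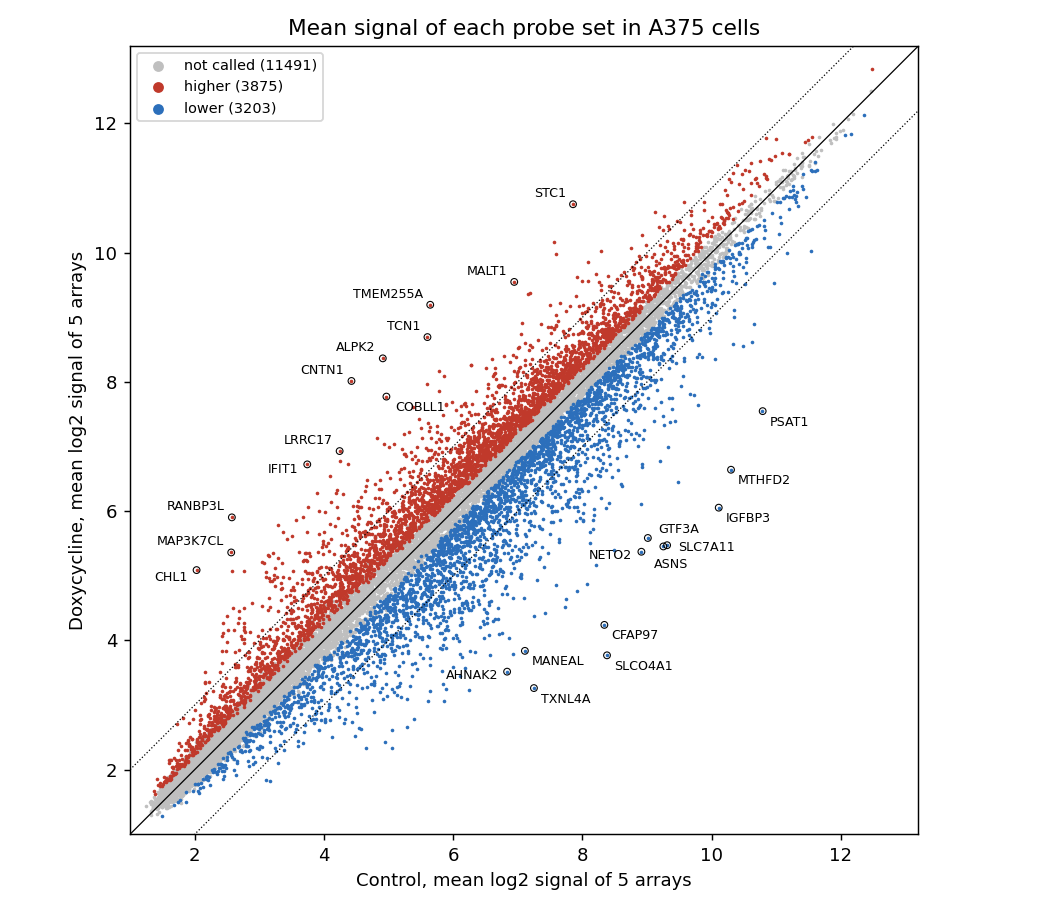
Mean log2 signal of each probe set in 5 doxycycline arrays (vertical axis) against 5 control arrays (horizontal axis), with higher (3875), lower (3203) and not called probe sets in different colours, the line of equality, and dotted lines at a 2-fold difference. The 12 highest and 12 lowest changes are named, from CNTN1 at a log2 fold change of 3.59 to SLCO4A1 at -4.61.

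The largest falls included genes of transport, amino acid and one-carbon metabolism. Values after gene names are log2 fold changes of doxycycline over control ± SE, with 5 arrays per group. SLCO4A1, an organic anion transporter, fell from 8.38 ± 0.09 to 3.77 ± 0.29 log2 units (SD, n = 5), a 24.5-fold difference. Below it came the cilia-associated gene CFAP97 (-4.10 ± 0.12), IGFBP3, a secreted binder of insulin-like growth factors (-4.06 ± 0.11), and TXNL4A, a component of the spliceosome (-3.99 ± 0.18). The cystine transporter SLC7A11 (-3.84 ± 0.15), asparagine synthetase ASNS (-3.80 ± 0.14), the mitochondrial folate enzyme MTHFD2 (-3.65 ± 0.09) and the serine synthesis enzyme PSAT1 (-3.24 ± 0.10) were among the 12 lowest. The remaining members were NETO2 (-3.54 ± 0.09), GTF3A, the factor that starts transcription of 5S rRNA (-3.43 ± 0.12), AHNAK2 (-3.32 ± 0.13) and MANEAL (-3.27 ± 0.14). Adjusted p values of these 12 genes reached at most 2.94e-10, for TXNL4A.

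At the other end, CNTN1, a neuronal adhesion molecule, rose from 4.43 ± 0.25 to 8.01 ± 0.32 log2 units (SD, n = 5), a 12-fold difference. TMEM255A (3.55 ± 0.09), the kinase gene ALPK2 (3.45 ± 0.10), RANBP3L (3.33 ± 0.18) and TCN1, which encodes a vitamin B12 carrier (3.09 ± 0.08), followed. The neural adhesion gene CHL1 (3.06 ± 0.12), IFIT1 (2.98 ± 0.10) and the secreted hormone gene STC1 (2.89 ± 0.08) also rose. COBLL1 (2.81 ± 0.13), MAP3K7CL (2.80 ± 0.10), LRRC17 (2.69 ± 0.14) and MALT1, a protease and scaffold of NF-kB signalling (2.60 ± 0.11), completed the 12 highest. RANBP3L had the largest adjusted p of these genes, 2.30e-09, and CHL1, RANBP3L and MAP3K7CL had a control signal below 2.80, the lowest first quartile of any array.

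Within the MYC network, the probe set of MYC itself rose from 6.06 ± 0.12 to 6.68 ± 0.18 log2 units (SD, n = 5), at an adjusted p of 1.63e-04. This measure cannot separate MYC from an Omomyc transcript, which derives from MYC. MGA, a MAX partner that represses transcription (-1.26 ± 0.11), MXI1, a MAX partner that opposes MYC (-0.88 ± 0.08), and MLXIP, a glucose-responsive factor that pairs with MLX (-0.55 ± 0.14), fell. MXD1, another MAX partner, fell by 0.27 ± 0.10 at an adjusted p of 0.0371, and the call was lost without doxycycline array 1 (adjusted p = 0.0777). The other 8 members did not pass the test. Their log2 fold changes were -0.08 for MAX, -0.06 for MLX, 0.07 for MNT, 0.08 for ZBTB17, 0.13 for MYCN, 0.13 for MLXIPL, 0.16 for MXD3 and 0.16 for MYCL. As a list, the network's 13 members did not pass (adjusted p = 0.386), with the same 1 higher and 4 lower when adjusted over the list alone.

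Genes that MYC is known to induce fell together. Of 48 measured, 30 fell and 1 rose, UTP20, with the same counts adjusted over the list alone. The median log2 fold change was -0.39 (adjusted p = 3.28e-11, and adjusted p = 0.022 with an estimated correlation). The folate carrier SLC19A1 (-2.87 ± 0.18), the ribosome assembly factor IMP4 (-2.13 ± 0.10), the mitochondrial chaperone HSPD1 (-2.02 ± 0.09) and the sterol-regulated TMEM97 (-1.71 ± 0.10) fell most. In ribosome biogenesis 22 of 42 genes fell and 1 rose, or 23 and 1 adjusted over the list alone (adjusted p = 6.66e-08, and adjusted p = 0.00757 with an estimated correlation). Fibrillarin, FBL, which methylates ribosomal RNA (-2.17 ± 0.08), RRP1B (-1.49 ± 0.09), NOP14 (-1.18 ± 0.09) and IMP3 (-1.16 ± 0.10) led this list. RNA polymerase I and III genes were mixed, with 13 of 31 lower and 6 higher, unchanged when adjusted over the list alone (adjusted p = 0.00617, and adjusted p = 0.0360 with an estimated correlation). Besides GTF3A the subunits POLR3G (-1.23 ± 0.11) and POLR1E (-1.0 ± 0.08) fell.

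Some ribosomal protein and translation factor genes fell as well. Of 35 ribosomal protein genes 12 fell and none rose (10 adjusted over the list alone), led by RPL10A (-0.78 ± 0.08) and RPL19 (-0.47 ± 0.09). This list passed with the preset correlation (adjusted p = 4.74e-04) and with the rotation test fry, which does not compare a list with other genes (adjusted p = 0.00360), but not with an estimated correlation (adjusted p = 0.445). Initiation and elongation factor genes fell in 15 of 34 cases and rose in 1, with the same counts adjusted over the list alone (adjusted p = 3.90e-04, and adjusted p = 0.125 with an estimated correlation). EIF4EBP1, an inhibitor of cap-dependent translation and itself an ATF4 target (-1.92 ± 0.11), and EIF1AX, which helps select the start codon (-1.16 ± 0.10), had the largest falls there.

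Most cell cycle genes fell. For G1/S and DNA replication, 40 of 45 genes fell and 1 rose, CCND3, against 40 and 2 adjusted over the list alone (adjusted p = 3.54e-24, and adjusted p = 7.44e-04 with an estimated correlation). The genes CDC45 (-2.35 ± 0.09), GINS2 (-2.19 ± 0.08), MCM2 (-2.11 ± 0.08) and CDT1 (-1.92 ± 0.18), which encode parts of the replicative helicase or its loader, fell most. All 46 genes of G2/M and mitosis fell, also when adjusted over the list alone (adjusted p = 8.27e-31, and adjusted p = 0.00205 with an estimated correlation). In front were MYBL2, a transcription factor of the G2/M programme (-2.19 ± 0.10), the cohesin protector SGO1 (-1.97 ± 0.10), the mitotic kinase PBK (-1.92 ± 0.10) and survivin, BIRC5 (-1.83 ± 0.13). Replication-dependent histone genes fell in 25 of 33 cases and rose in 1 (26 and 1 adjusted over the list alone), for example H2AC8 (-1.64 ± 0.16) and H1-5 (-1.56 ± 0.14). The histone list passed at an adjusted p of 3.28e-11 but not under the stricter setting (adjusted p = 0.126 with an estimated correlation), and these genes share much of their sequence.

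Among CDK inhibitors and related pocket proteins 3 of 10 rose and 3 fell, unchanged when adjusted over the list alone, and the list did not pass (adjusted p = 0.713). The pocket protein RBL1 (-1.24 ± 0.10), the phosphatase CDKN3 (-0.96 ± 0.11) and CDKN2A (-0.54 ± 0.16) fell. CDKN1B, which restrains CDK2 (0.52), CDKN1A, the p53-induced inhibitor (0.41), and RB1 (0.27) rose. Targets of p53 went both ways, with 14 of 28 higher and 5 lower, or 15 and 5 adjusted over the list alone (adjusted p = 0.112). TP53INP1, which promotes autophagy and cell death (1.36 ± 0.13), and the kinase PLK2 (0.94 ± 0.08) rose, while the nuclease AEN fell (-1.56 ± 0.09). Of the apoptosis regulators 8 of 24 rose and 5 fell, 9 and 5 adjusted over the list alone (adjusted p = 0.509). CFLAR, an inhibitor of caspase 8 (0.78 ± 0.08), rose, and BOK, which promotes cell death (-1.09 ± 0.18), and BCL2, which opposes it (-0.85 ± 0.13), fell.

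**Figure D2:**
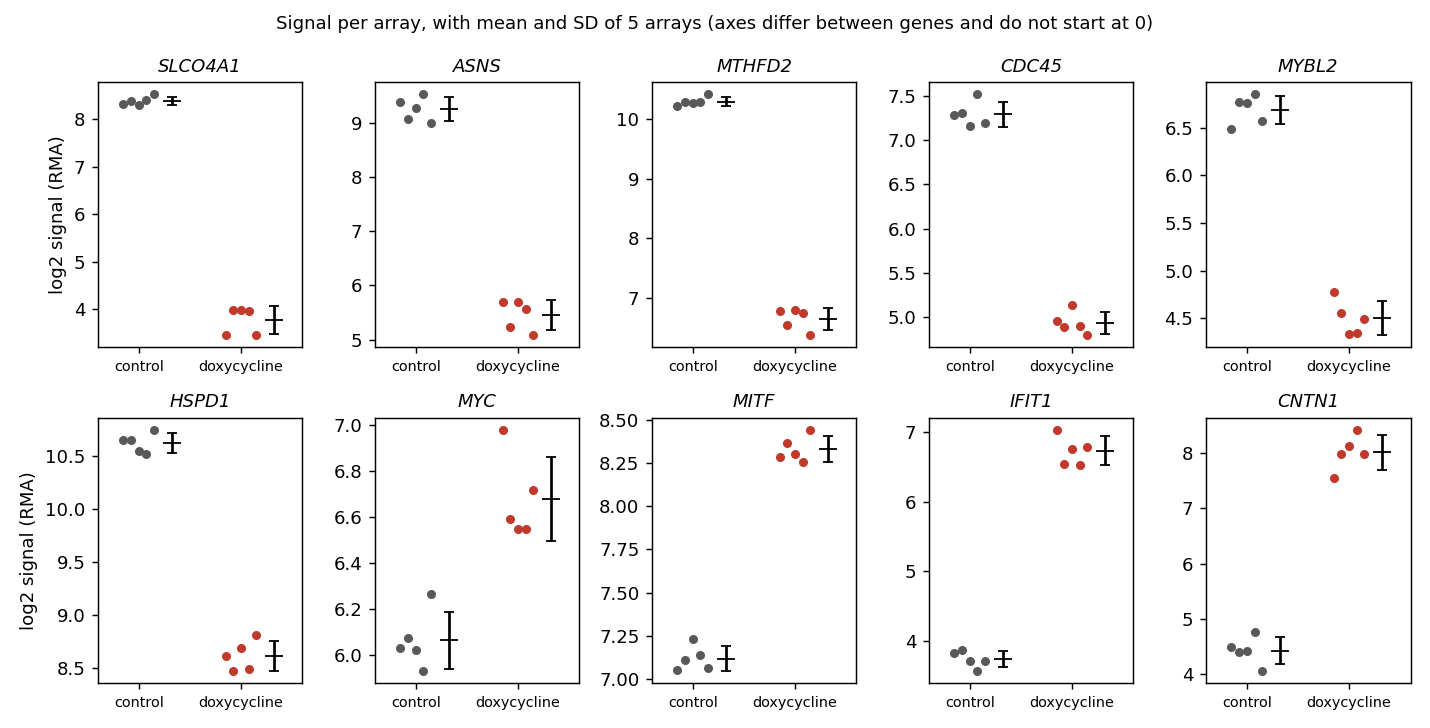
Log2 signal of 10 named genes on each of 5 control and 5 doxycycline arrays (points), with mean and SD beside them and a separate vertical axis per gene that does not start at 0. The groups did not overlap for any of these genes, and MYC had the smallest difference, with means of 6.06 and 6.68. For SLCO4A1, ASNS, MTHFD2, IFIT1 and CNTN1 the naming rule required this lack of overlap.

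Amino acid supply genes fell strongly. In the ATF4 and amino acid response list 28 of 32 genes fell and none rose, also when adjusted over the list alone. The median of the list was -0.91 (adjusted p = 8.85e-21, and adjusted p = 7.44e-04 with an estimated correlation). Besides SLC7A11, the mitochondrial folate enzyme ALDH1L2 (-3.10 ± 0.08), the pseudokinase TRIB3 (-3.04 ± 0.13) and mitochondrial PEP carboxykinase PCK2 (-2.37 ± 0.13) showed the largest falls. All 10 genes of glutamine and serine metabolism fell, with the same count adjusted over the list alone (adjusted p = 5.58e-10, and adjusted p = 0.00486 with an estimated correlation). ASNS and PSAT1 led them, followed by the glutamine carriers SLC38A1 (-2.15 ± 0.10) and SLC1A5 (-2.03 ± 0.08). Nucleotide synthesis genes fell in 22 of 27 cases and none rose, 23 adjusted over the list alone (adjusted p = 4.80e-15, and adjusted p = 0.00205 with an estimated correlation). They included RRM2, a subunit of ribonucleotide reductase (-2.42 ± 0.08), the purine enzyme PAICS (-1.84 ± 0.12) and thymidine kinase TK1 (-1.68 ± 0.14).

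Other metabolic lists moved in both directions. Of 9 polyamine genes 2 rose and 3 fell, as they did adjusted over the list alone (adjusted p = 0.829). The risers, SAT1 (2.20 ± 0.08) and SMOX (1.2 ± 0.09), break polyamines down, whereas the spermine synthase gene SMS fell (-1.59 ± 0.08). In glycolysis 8 of 20 genes fell and 4 rose, 9 and 5 adjusted over the list alone (adjusted p = 0.255), with phosphofructokinase PFKL lower (-1.67 ± 0.10) and aldolase ALDOC (0.95 ± 0.07) and the glucose carrier SLC2A3 (0.93 ± 0.08) higher. For cholesterol and fatty acid synthesis, 9 of 24 genes fell and 7 rose, 12 and 8 adjusted over the list alone (adjusted p = 0.0805). Fatty acid synthase FASN (-1.32 ± 0.11), the sterol isomerase EBP (-1.15 ± 0.09) and the elongase ELOVL6 (-1.01 ± 0.09) fell.

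Some nuclear-encoded mitochondrial genes fell, nearly all of them by less than 2-fold. Of 42 oxidative phosphorylation genes 21 fell and none rose, 23 adjusted over the list alone (adjusted p = 2.13e-04, and adjusted p = 0.184 with an estimated correlation), for example ATP5F1D (-0.90 ± 0.10) and COX5A (-0.74 ± 0.08). Mitochondrial ribosome and translation genes fell in 23 of 49 cases and rose in 3, 25 and 3 adjusted over the list alone (adjusted p = 5.96e-06, and adjusted p = 0.126 with an estimated correlation), led by MRPS34 (-1.68 ± 0.10) and MRPL3 (-0.98 ± 0.08). The endoplasmic reticulum unfolded protein response had 9 of 22 genes lower and 4 higher, unchanged when adjusted over the list alone (adjusted p = 0.255). HERPUD1, which helps clear misfolded proteins (-0.63 ± 0.08), and the stress transcription factor XBP1 (-0.57 ± 0.08) fell. Heat shock genes were lower in 6 of 22 cases and higher in 2, as they were adjusted over the list alone (adjusted p = 0.255), with the small chaperone HSPB1 higher (0.87 ± 0.08) and HSPA4L lower (-0.61 ± 0.14).

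Melanoma state genes also changed. MITF, the lineage transcription factor of melanocytes, rose from 7.12 ± 0.07 to 8.33 ± 0.07 log2 units (SD, n = 5). With it rose the semaphorin SEMA6A (1.39 ± 0.12) and the protease CAPN3 (1.17 ± 0.14). In the MITF and pigmentation list 9 of 27 genes rose and 3 fell, MLPH, IRF4 and MREG, against 10 and 3 adjusted over the list alone. The list missed the threshold over all probe sets (adjusted p = 0.0805) and passed without the probe sets under the 25th percentile of signal (adjusted p = 0.0126). Genes of the undifferentiated and invasive state rose in 20 of 37 cases and fell in 8, 21 and 9 adjusted over the list alone. The cytokine IL6 (2.5 ± 0.18) and fibronectin FN1 (2.39 ± 0.10) rose, while FOSL1, an AP-1 subunit (-1.60 ± 0.09), and SNAI2, a repressor of epithelial genes (-1.54 ± 0.16), fell. That list passed at an adjusted p of 0.0375 and was lost under the other setting (adjusted p = 0.101 with an estimated correlation) and without control array 4 (adjusted p = 0.0609).

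Genes downstream of MAPK signalling, which mutant BRAF drives in this line, rose in 10 of 25 cases and fell in 3, 11 and 3 adjusted over the list alone (adjusted p = 0.0311, and adjusted p = 0.140 with an estimated correlation). The transcription factors EGR1 (1.76 ± 0.09) and FOS (1.23 ± 0.14) and the receptor EPHA4 (1.27 ± 0.09) rose, whereas PHLDA2 fell (-1.77 ± 0.12). EGR1 and FOS also belong to the immediate early genes, which respond within minutes to handling. Of 16 such genes 10 rose and 1 fell, ATF3, with the same counts adjusted over the list alone (adjusted p = 8.00e-04, and adjusted p = 0.126 with an estimated correlation). ZFP36, which destabilises cytokine RNAs, was among those that rose (1.5 ± 0.09). Without the members shared with other lists the MAPK list did not pass (adjusted p = 0.246).

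Interferon response genes rose as a group. Of 37 measured 24 rose and 5 fell, also when adjusted over the list alone. The median of the list was 0.57 (adjusted p = 1.32e-06, and adjusted p = 0.00646 with an estimated correlation). IFIT1, SAMD9L (1.99 ± 0.12), IFIT2 (1.95 ± 0.09) and IFI6 (1.70 ± 0.13), all antiviral, rose most, and the 5 that fell were OAS3, IFIT5, ISG20, MX2 and USP18, a brake on interferon receptor signalling. Antigen presentation genes rose in 10 of 22 cases and none fell, also when adjusted over the list alone (adjusted p = 0.00314, and adjusted p = 0.163 with an estimated correlation). TAPBP, which loads peptides onto MHC class I (0.94 ± 0.08), the immune checkpoint ligand CD274 (0.84 ± 0.18) and the peptide-trimming ERAP2 (0.65 ± 0.14) were examples. NF-kB and secreted inflammatory genes rose in 13 of 28 cases and fell in 3, 14 and 4 adjusted over the list alone (adjusted p = 0.0163, and adjusted p = 0.126 with an estimated correlation), a call also lost among the probe sets above the median signal (adjusted p = 0.0962). The chemokine CCL2 rose (2.23 ± 0.09), and IL24 (-1.69 ± 0.09) and the angiogenic factor VEGFA (-1.52 ± 0.08) fell.

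Lysosome and autophagy genes rose in 20 of 36 cases and fell in 2, LAMP3 (-1.31 ± 0.09) and GLA, against 20 and 3 adjusted over the list alone (adjusted p = 4.99e-04, and adjusted p = 0.0360 with an estimated correlation). The cathepsins CTSK (1.49 ± 0.09), CTSL (1.06 ± 0.08) and CTSB (0.90 ± 0.08), proteases of the lysosome, rose most. In the extracellular matrix and adhesion list 18 of 32 genes rose and 6 fell, 20 and 7 adjusted over the list alone (adjusted p = 0.00279, and adjusted p = 0.126 with an estimated correlation). The proteoglycan VCAN (2.10 ± 0.13) and the basement membrane protein NID2 (1.67 ± 0.11) rose, while the proteoglycan BGN (-2.04 ± 0.10) and the adhesion molecule L1CAM (-1.64 ± 0.11) fell.

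Hypoxia response genes went both ways, with 9 of 18 higher and 5 lower, unchanged when adjusted over the list alone (adjusted p = 0.467). BNIP3L, which marks mitochondria for removal, rose (0.78 ± 0.08), and MXI1 fell. Of 15 core clock genes 5 rose and 4 fell, 5 and 5 adjusted over the list alone (adjusted p = 0.964). PER2 (1.29 ± 0.10) and BMAL1 (1.08 ± 0.09), of opposite arms of the clock, both rose, and the repressors NR1D1 (-1.29 ± 0.11) and BHLHE41 (-1.09 ± 0.15) fell.

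**Figure D3:**
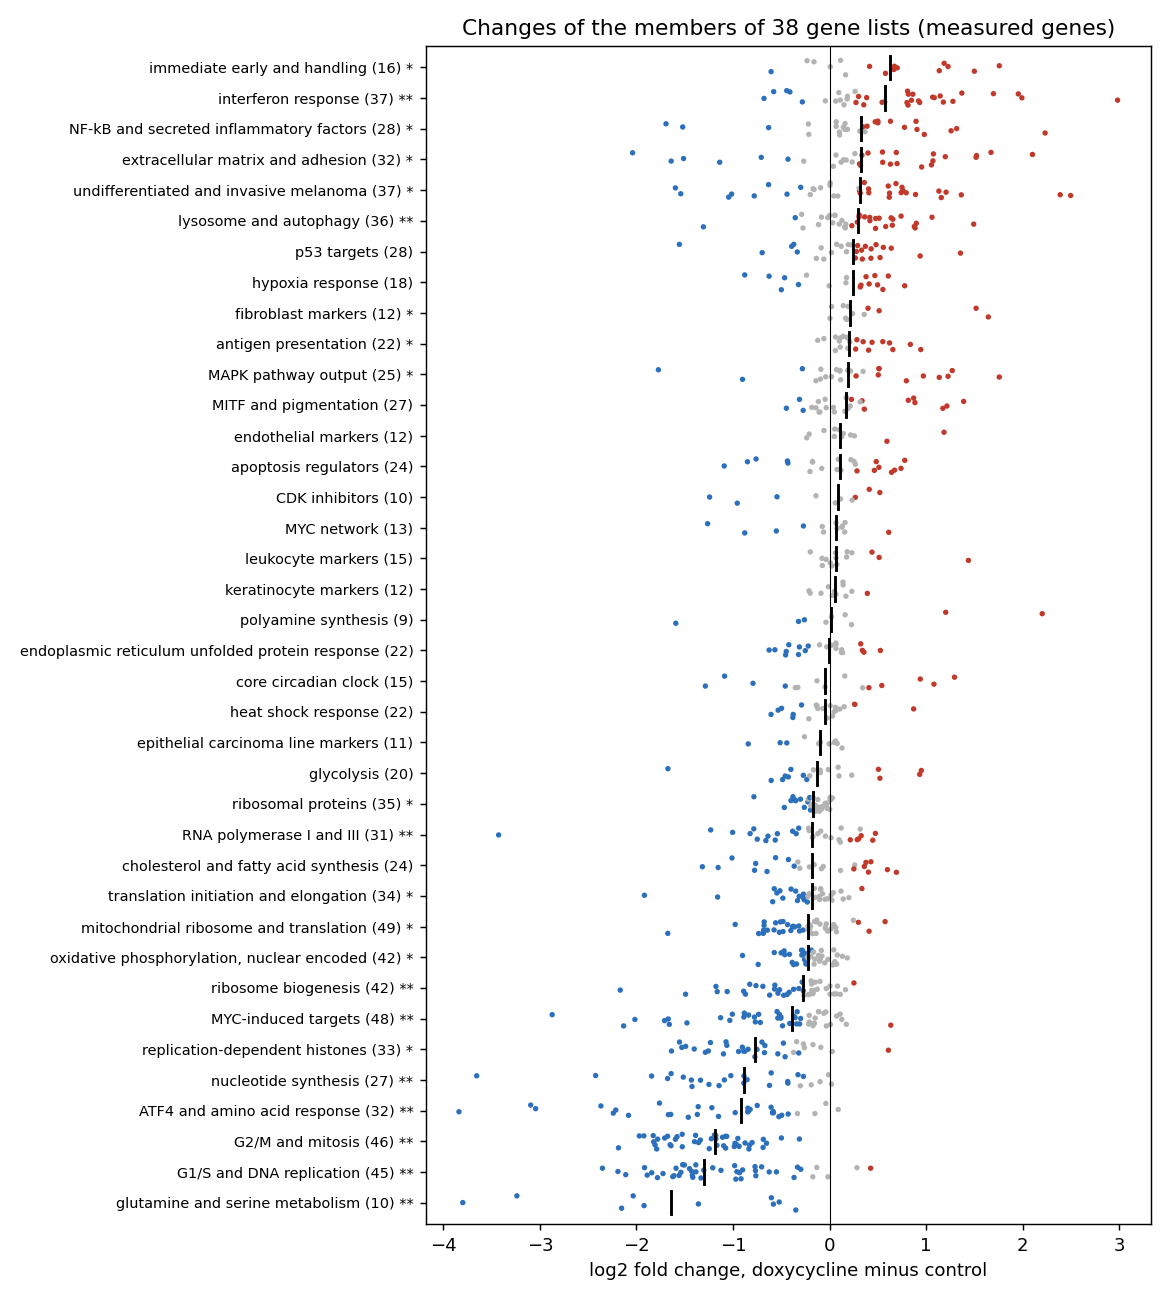
Log2 fold changes of the measured members (points, number in brackets) of 38 gene lists, with a bar at each list's median, coloured where a gene was higher or lower and grey where it was not called, where 1 star marks lists past an adjusted p of 0.05 and 2 stars those also past it with an estimated correlation. Medians ran from -1.64 for glutamine and serine metabolism to 0.62 for the immediate early genes.

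Markers of other cell types were mostly dim and few of them changed. Fibroblast markers rose in 4 of 12 cases and none fell, also when adjusted over the list alone, namely PDGFRA (1.64 ± 0.14), LUM (1.52 ± 0.10), ACTA2 and DCN (adjusted p = 0.0216, and adjusted p = 0.143 with an estimated correlation). Without LUM and DCN, which the matrix list also holds, that list did not pass (adjusted p = 0.102). Endothelial markers rose in 2 of 12 cases, KDR (1.19 ± 0.12) and ROBO4 (0.59 ± 0.11), with the same count adjusted over the list alone (adjusted p = 0.386). Leukocyte markers rose in 3 of 15, LYZ (1.44 ± 0.14), CD14 (0.51 ± 0.09) and CD79A (0.44 ± 0.15), or in 2 adjusted over the list alone (adjusted p = 0.366), and the pan-leukocyte marker PTPRC stayed at 2.07 ± 0.30 log2 units with doxycycline (SD, n = 5). Of 12 keratinocyte markers KRT5 rose (0.39 ± 0.12), and 0 passed adjusted over the list alone (adjusted p = 0.858). Of 11 epithelial markers 3 fell, KRT8 (-0.84 ± 0.08), KRT7 (-0.51 ± 0.09) and ESRP1, with the same count adjusted over the list alone (adjusted p = 0.112). The calls of CD79A and KRT5 were lost when single arrays were left out, for example CD79A without doxycycline array 1 (adjusted p = 0.0676) and KRT5 without control array 3 (adjusted p = 0.0646).

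The array of doxycycline replicate 1 stood apart, with a first quartile of 2.94 log2 units against 2.80 to 2.87 on the other arrays and a mean correlation of 0.991 with its group against 0.993 to 0.995 for the other 4 doxycycline arrays. Without it 7237 probe sets changed, 1249 of them at least 2-fold, and 23 interferon, 10 antigen presentation and 4 fibroblast genes were higher. With all arrays 1202 probe sets changed at least 2-fold, 452 higher and 750 lower. The 5 values of each group did not overlap for 5306 probe sets (28.6%), where chance gives 0.794%. Of 38 lists 22 passed, 9 higher and 13 lower, and 10 of 38 did so with an estimated correlation, 2 higher (interferon response and lysosome) and 8 lower (MYC-induced targets, ribosome biogenesis, RNA polymerase I and III, nucleotide synthesis, glutamine and serine metabolism, both cell cycle lists and the ATF4 list). Requiring more than a 1.2-fold change lowered the number of changed probe sets from 7078 to 3360. With that floor MXD1, MLXIP, RPL19, CDKN2A, HSPA4L, KRT5 and CD79A were no longer called, and an exact permutation test per probe set lost MXD1, MLXIP, CDKN2A, KRT5 and CD79A.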

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

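The search for single arrays far from the other 4 of their group covered 278 sets of values of the named genes, and 14 exceeded the critical value of 0.71 for Dixon's ratio of gap to range, where chance gives about 13.9. In control cells, array 1 was highest for LUM (ratio 0.825) and lowest for PFKL (0.777) and PDGFRA (0.756), and array 5 was lowest for ALDOC (0.728). Doxycycline array 1 was lowest for MGA (0.818) and highest for TMEM97 (0.742) and MCM2 (0.733). Doxycycline array 2 was lowest for SAT1 (0.729), and array 3 was lowest for RRM2 (0.784) and ZBTB17 (0.72). Doxycycline array 4 was lowest for SMOX (0.846), PLK2 (0.825) and CD79A (0.715), and array 5 was highest for ATP5F1D (0.794). ZBTB17 did not pass the test between groups. The other 13 genes did. CD79A, at 3.09 log2 units on doxycycline array 4 against 3.71 to 3.96 on the rest of its group, lay within the control range on that array.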

How the results depend on the processing

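The count of changed probe sets stayed within 1.5 times of 7078 under all alternatives but treat, from 5252 at an adjusted p under 0.01 to 7696 with array weights. Leaving out 1 array gave 6378 to 7237. Requiring more than a 1.2-fold change with treat left 3360 (1633 higher and 1727 lower), which follows from the floor itself, since the median size of the called changes was 0.52 log2 units. Probe sets changed at least 2-fold numbered 840 among those above the median signal and 1193 to 1249 under the other alternatives. The share that rose depended on scaling, with 3366 higher and 3559 lower after cyclic loess and 4393 higher and 2916 lower after median centring.

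Of 38 lists, 22 passed as reported and 20 to 23 under most alternatives, but 10 with an estimated correlation and 36 with fry, which does not compare a list with other genes. MITF and pigmentation passed without the dimmest probe sets, and the undifferentiated melanoma list was lost there, after median centring, on ranks and without control array 4. Over all alternatives named genes kept direction and side of the threshold in 2992 comparisons, and lost the call in 34, mostly MXD1, CD79A and KRT5. MAX gained one with exact permutation (adjusted p = 0.0278). MNT, never called, ran from -0.0018 without doxycycline array 5 to 0.12 without control array 5. The causes were not tested.

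Replicate numbers did not pair the arrays by the criterion set in advance, a correlation over 0.1 for every equal number. That criterion does not address negative correlations, and all those of equal numbers were negative. Correlations of deviations from the group mean were -0.437 to -0.00746 for equal numbers and -0.247 to 0.159 for others, and 0 of 5 control arrays correlated best with their own number. With a replicate block 6476 probe sets changed, 3499 higher and 2977 lower, 1202 of them at least 2-fold, and 22 lists passed. Centring on control probe sets was not run, because none could be recognised in the values used, and treat, exact permutation and the stricter threshold give no list value. Signal near background limits dim genes such as the markers of other cell types.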

Other observations

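The tests of endoplasmic reticulum stress, secreted interferon, doxycycline without Omomyc and the MYC probe set, and all gene families, were chosen after the results they address were seen. Genes in the next paragraph were named after their values were seen, from 322 groups of at least 8 genes that share the start of their symbol. Of these families 15 passed at the preset correlation and 0 did so with an estimated one.

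Protocadherin beta genes, neuronal adhesion molecules that lie next to each other, rose in 14 of 16 cases with a median log2 fold change of 0.70 (adjusted p = 7.42e-05, and adjusted p = 0.426 with an estimated correlation), led by PCDHB14 (1.26 ± 0.08, SE). Metallothionein genes, which encode metal-binding proteins, fell in 9 of 13 cases (adjusted p = 0.00128, and adjusted p = 0.526 with an estimated correlation), among them MT2A, from 11.2 to 9.99 log2 units. Members of both families share sequence, so probe sets may not be independent. The medians of both families kept their sign under 3 other scalings (0.66 to 0.74 and -0.57 to -0.50). Those scalings moved the medians little and do not address shared sequence. Of 9 genes of the EXOSC family, most of which encode the RNA exosome, 8 fell (adjusted p = 0.00203, and adjusted p = 0.426 with an estimated correlation), with EXOSC8 at -1.28 ± 0.12. HOXD genes, which pattern limbs and trunk, fell in 5 of 8 cases (adjusted p = 0.0202, and adjusted p = 0.506 with an estimated correlation), with HOXD13 at -2.41 ± 0.14. Medians of the EXOSC and HOXD families also stayed below 0 under those scalings.

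Genes of aminoacyl-tRNA synthetases, which load tRNAs, differed between those named as cytosolic, some of them shared with mitochondria, and those named as mitochondrial. Of 14 enzymes named as cytosolic 13 fell, with a mean log2 fold change of -0.97 and an SD of 0.70 over genes, and IARS1 fell most (-2.81 ± 0.09). Of 15 mitochondrial enzymes 3 fell and 1 rose, with a mean of -0.14 (SD 0.31). The hypothesis of a larger fall of the cytosolic enzymes was met in a two-sided permutation test over genes, p = 5e-05, although genes are not independent replicates. Most of the cytosolic enzymes are also members of the ATF4 list reported above, and none of the mitochondrial ones is. The test therefore repeats in part the fall of that list. The groups also differed in signal, for which the test did not allow. Most mitochondrial genes, such as AARS2 at 3.61 log2 units in control, were dimmer than RARS1 (8.10), the dimmest cytosolic one. Dim signal compresses fold changes.

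A second hypothesis, that lower NR1D1 and NR1D2 released their targets besides BMAL1, was not met. Of NPAS2, CLOCK and NFIL3 only 1 was higher, NPAS2 (0.41 ± 0.07), while NFIL3 fell (-0.69 ± 0.09). Across 17466 pairs of neighbouring genes, log2 fold changes correlated at r = 0.0921 (Spearman's rho 0.0906), against at most 0.0241 in 1000 shuffled orders, and at 0.0767 over 15600 pairs whose symbols start differently. The correlation was 0.0613, 0.0347 and 0.00956 at 2, 5 and 10 genes apart, so a chance order of genes is excluded, but it is a correlation across genes and a weak one.

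The ATF4 target genes fell together, and RNA of ATF4 itself, a member of that list, fell as well (-0.59 ± 0.09, SE). A fall of the endoplasmic reticulum stress genes as large as that of the ATF4 list is argued against by their median of -0.0054. Its quartiles were -0.32 and 0.12, against a median of -0.91 for the ATF4 list. A smaller fall of this stress stays open, because 9 of its 22 genes fell and 4 rose, and fry passed the list as lower (adjusted p = 0.0073). Less glucose used up in the doxycycline cultures predicted that TXNIP and ARRDC4, which rise with glucose, would both be higher, and this was not met. TXNIP fell (-3.18 ± 0.17), and ARRDC4 was at -0.29 without passing the test. This cause still cannot be told apart from the others, because MLXIP, the activator of both genes, fell as well. The call of MLXIP was lost with treat and with exact permutation. Lower use of amino acids in slower cultures, an effect of doxycycline itself and a direct effect of blocking MYC, a biological explanation, may each hold. These were not tested.

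For the rise of the interferon response genes, raised dim signal on doxycycline array 1 is excluded, since 23 of them were higher without that array. Secreted interferon stays open, because 2 of 21 measured interferon genes were higher, IFNA1 (0.27 ± 0.08) and IFNA8 (0.26 ± 0.09), and 1 was lower, IFNL3 (-0.31 ± 0.09). Of 7976 other genes in the same range of signal 11.5% were higher, so 2 of 21 was no more than their share (exact hypergeometric test, p = 0.715). IFNL3, at 4.84 log2 units in control, stretched that range, while the median interferon gene lay at 2.01 with doxycycline. IFNA1 and IFNA8 stayed below 2.80, the lowest first quartile of any array, in both groups. Neither the calls nor the comparison can therefore decide. The comparison with other genes was set only after these calls were seen, and the calls alone would have met the test as first written. An effect of doxycycline that does not need Omomyc cannot be told apart either, because no array is labelled as treated cells without the transgene. Loss of repression by MYC, a biological explanation, may act here and was not tested.

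The MYC probe set was higher by 0.61 log2 units, and by 0.54 without doxycycline array 1. Hybridisation of the Omomyc transcript to the MYC probe set cannot be told apart from a rise of MYC itself, since probe sequences were not used here. Release of MYC from its own repression is a biological explanation and may hold too, untested.

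A chance division of the arrays as the origin of the counts was excluded with 100 of the 126 splits of the 10 arrays into groups of 5, the real one included. The real split alone, 1 of 100, called 7078 probe sets or 1202 changed at least 2-fold, and the highest of the others called 0. As 5 arrays cannot be divided evenly, every other split keeps part of the treatment difference and moves the rest into the spread within groups, where the median residual SD was 0.205 to 0.225 against 0.165. That spread lowers the gene counts of the other splits, so their 0 does not measure how many false calls the real comparison holds. The real split was also the 1 split with 22 lists past the threshold. Every other split also passed lists at the preset correlation, from 3 to 20, while calling 0 probe sets. Those with 20 moved 1 array of each group, and those that moved 2 reached at most 16.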
